A study of Homo sapiens with 3 samples.

How the data were processed

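The study measured RNA of the human breast cancer cell line T47D on Affymetrix expression arrays of 54675 probe sets, with 1 array for each of 3 groups (vehicle, estradiol and tamoxifen). Groups were taken from the treatment given in the labels. Per the labels' protocols, total RNA was isolated on columns and labelled with biotin by the manufacturer's protocol.

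The deposited values are on a log2 scale and were made by the authors with RMA (robust multi-array averaging, which corrects background, quantile normalizes and summarises probes), per the submitters' processing notes, which give no version. The values carry both signs around 0, so a centre per probe set had been subtracted before deposit, a step that no label records. The centre was not the median of these 3 arrays, which was 0 (to within 1e-05) in 91 probe sets. In 802 probe sets a pair of arrays had exactly opposite values (to within 2e-06), as a median over an even number of arrays would give, so arrays not analysed here probably entered it. Signal levels cannot be recovered from such values, whereas the difference between 2 arrays of a probe set is kept. Log base 2 is taken from RMA and cannot be checked on centred values, and folds depend on it. RMA shrinks differences of dim probe sets, and how dim a probe set was is unknown here. The software behind RMA and its settings are not given in the sources used here.

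Gene symbols came from the array's annotation table. Of the probe sets, 41097 had 1 gene symbol, 1801 had several and 11777 were unnamed here, including the 62 control probe sets. Entrez identifiers of 41043 were matched to a gene table of assembly GRCh38.p14, used for current names and gene lengths only, and 0 symbols changed. Probe sets with several genes were left out. No coordinates are printed, since no build is stated for the array values.

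The difference between 2 arrays was taken per probe set and the median over the probe sets of a gene was its value, for 19775 genes, of which 10523 had at least 2 probe sets and 9252 had 1. A gene was past the cutoff at an absolute log2 difference of at least 1. Counts over all genes are given for the values as deposited, and gene values, list values and counts of list members after subtracting the median difference of all genes, unless stated otherwise. An array was said to stand apart in a gene if it differed by at least 1 from both others in the same direction while these differed by less than 0.5. With 1 array per group no test was possible. Agreement between the probe sets of a gene was the available measure of technical error: 2 random probe sets of the same gene correlated across genes at 0.333 for estradiol minus vehicle, 0.234 for tamoxifen minus vehicle and 0.0994 for tamoxifen minus estradiol.

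The 41 gene lists (pathways, cell type markers and estrogen-responsive genes, 674 of 754 memberships measured) and the rule for named genes were fixed before the data were examined. The genes named are the 12 highest and 12 lowest per comparison, up to 4 members of each list that stood apart, taken from the side of its median, and 22 genes fixed in advance, of which 19 were measured. A few others are said to be named after their values were seen. A list stood apart if its median lay below percentile 2.5 or above 97.5 of 10000 random lists of the same size drawn from all genes, which is a description of these arrays. By chance 5% of lists of independently varying genes do so, and the share can be higher where members vary together.

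The plan also held a filter on signal level, random lists matched on level and the use of the probe set with the highest mean level. None of these could be applied to values without levels, so no filter was used, random lists were unmatched on level and the median over probe sets replaced the brightest one. Low signal therefore remains in every count.

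The correlation of both differences from vehicle was set against 100 simulations of unchanged arrays that share the vehicle array, with independent normal noise of the same SD on each of the 3 arrays, taken from the tamoxifen minus estradiol differences. The calculations were tested on simulated data for 19775 genes. A planted difference of 1.5 was recovered past the cutoff in 89%, 90% and 99% of genes and one of 2 in 99%, 98% and 100% for estradiol against vehicle, tamoxifen against vehicle and tamoxifen against estradiol. Lists of 20 genes shifted by 0.5 stood apart in 100 of 100 cases in each comparison, and unshifted lists in 7, 1 and 2 of 100. The simulated values were the observed probe set differences shuffled over probe sets, so they keep every observed difference, and 3.30%, 3.89% and 0.230% of unshifted genes passed the cutoff. These shares are close to the observed ones of 3.32%, 3.26% and 0.212%, and the simulation measures recovery and not the rate of false calls. Alternatives were a cutoff of 1.5-fold, leaving out probe sets with the suffix _s_at or _x_at, which can match several transcripts, and a rank correlation. Chosen after seeing the data were the mean over probe sets, subtraction of the all-gene median, a cutoff of 4 all-gene spreads, the requirement that every one of at least 2 probe sets pass, and random lists matched on the number of probe sets. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used.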

Results

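Early transcript levels were measured in T47D, an established human breast cancer cell line that expresses the estrogen and progesterone receptors. Before treatment, the cells were kept for 4 h in medium with 10% serum stripped of steroids by charcoal. They then received 0.1% ethanol as vehicle, 1 uM estradiol (the natural ligand of the estrogen receptor) or 1 uM tamoxifen (a selective estrogen receptor modulator used against breast cancer) for 3 h. The RNA of each treatment was hybridised to 1 Affymetrix array of 54675 probe sets, so that 3 arrays were compared and no group had a replicate. No difference below has a replicate check, and no p-value or SD between samples could be given. The number of arrays limits the precision of every value.

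The deposited values were log2 expression values centred per probe set, with array medians of -0.0070 for vehicle, -0.011 for estradiol and 0.081 for tamoxifen. Levels were not kept in these values, whereas differences between arrays were. Log base 2 was taken from the RMA method named by the submitters, could not be checked on centred values, and underlies every fold. The median difference over 19775 genes was -0.0057 for estradiol minus vehicle, 0.10 for tamoxifen minus vehicle and 0.11 for tamoxifen minus estradiol. Gene and list values below are log2 differences relative to these medians, and folds were computed from them. A relative value between 0 and minus the median has the opposite sign in the values as deposited. The spread of all genes (the scaled median absolute deviation) was 0.33, 0.36 and 0.20 for the 3 comparisons in the same order.

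The vehicle array differed from both treated arrays in Affymetrix control probe sets for ribosomal RNA, spike transcripts and the ends of 2 abundant messenger RNAs. Values of control probe sets are given as deposited. The median of 3 probe sets for 18S ribosomal RNA was 1.86 higher on the estradiol array and 1.96 higher on the tamoxifen array than on the vehicle array. The 5' probe set of 28S ribosomal RNA was 2.08 and 2.20 higher, whereas its 3' probe set differed by 0.074 and 0.045 and its middle one by 0.034 and -0.010. The 24 probe sets of bacterial polyadenylated spike transcripts had medians of 0.70 and 0.49. Between the tamoxifen and estradiol arrays, 18S, the 5' probe set of 28S and the polyadenylated spikes differed by 0.043, 0.12 and -0.15, with 24 of 24 spike probe sets lower on the tamoxifen array. The 3' signal of ACTB (beta actin) minus its 5' signal was -0.78 on the estradiol array and -0.77 on the tamoxifen array relative to vehicle, and the corresponding values of GAPDH, a glycolytic enzyme, were -0.53 and -0.54. Between the treated arrays the values were 0.0058 for ACTB and -0.0059 for GAPDH. Every comparison with vehicle rests on this array, and without it tamoxifen against estradiol is the comparison that remains.

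**Figure D1:**
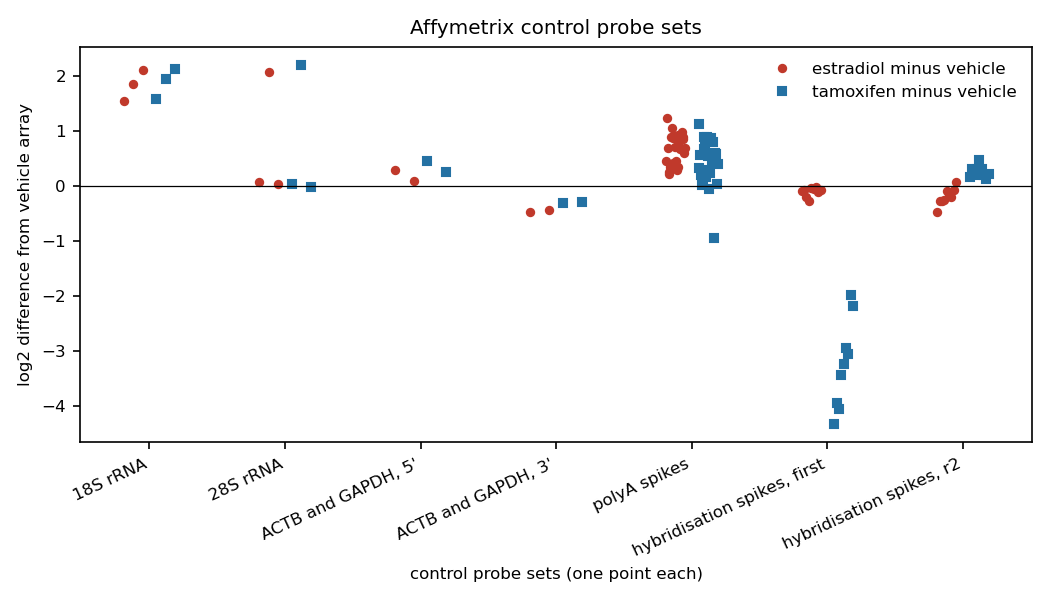
Log2 difference from the vehicle array (y axis, as deposited) of Affymetrix control probe sets, grouped by kind (x axis), with a point per probe set for the estradiol (circles) and tamoxifen (squares) arrays. The 18S, 5' 28S and most polyadenylated spike points lie above 0 on both treated arrays, and the 9 first hybridisation spike probe sets lie between -4.32 and -1.97 on the tamoxifen array.

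The first comparison asks which transcripts differed between estradiol and vehicle after 3 h. Several genes known to be induced by estrogen were higher on the estradiol array: KCNK5, a potassium channel, was 5.43-fold higher than on the vehicle array, MYC, a growth-promoting transcription factor, 4.54-fold, PGR, the progesterone receptor, 2.78-fold and CXCL12, a chemokine, 2.40-fold. TFF1, a secreted trefoil peptide and textbook estrogen target, was instead 4.51-fold lower. Stress genes were among the lowest: CHAC1, which degrades glutathione, was 13.0-fold lower and DDIT3, the stress transcription factor CHOP, 7.55-fold lower. Inflammatory genes were also low, with CCL20, a chemokine, 7.58-fold and TNFAIP3, a feedback inhibitor of NF-kB, 4.95-fold lower. The highest values were those of SYBU (syntabulin, 8.20-fold), GJA1 (connexin 43, 6.35-fold) and TMED2, a protein of secretory transport, for which 1 of 3 probe sets read -0.071 against 2.63 and 3.09 for the others.

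Of 37 measured genes in the list of estrogen-induced genes, 26 lay above the all-gene median on the estradiol array and 11 below, with a list median of 0.41 that exceeded all 10000 random lists of that size (percentile 100). At least 2-fold differences were seen for 7 members above and 2 below, the latter being TFF1 and CTSD (-1.08), which is also in the lysosome list. SIAH2, a ubiquitin ligase, had a value of 0.86, GREB1, a cofactor of the estrogen receptor, 0.93, EGR3, an early growth response factor, 0.65 and PDZK1, a scaffold protein, 0.56. The GREB1 probe sets ranged from 0.16 to 1.64. When probe sets with the suffix _s_at or _x_at, which can match more than 1 transcript, were left out, 26 members remained with a median of 0.0087 at percentile 55.12, and the list no longer stood apart. KCNK5 and MYC were among the members left out, since each had 1 probe set, with the suffix _s_at. CCND1, the gene of cyclin D1, had 2 probe sets of opposite sign, at 0.98 (suffix _s_at) and -0.32 (suffix _at). ESR1, which encodes the estrogen receptor alpha, had a value of 0.21 over 9 probe sets.

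Mitotic genes formed another group that stood above random lists. Of 20 G2/M genes, 18 lay above and 2 below the all-gene median, 5 of them at least 2-fold above, with a list median of 0.68 (percentile 100). CENPE, a kinetochore motor, was 2.47-fold, TOP2A, a DNA topoisomerase, 2.27-fold and KIF20A, a mitotic kinesin, 2.18-fold higher on the estradiol array. CDK1, the mitotic kinase, was 4.06-fold higher as the median of 4 probe sets that ranged from 0.45 to 3.13. Targets of the aryl hydrocarbon receptor had a list median of 0.29 (8 of 10 above 0, percentile 99.19), led by the cytochrome P450 genes CYP1B1 (1.92) and CYP1A1 (0.93). Heat shock genes, which encode chaperones, had a median of 0.23 (8 of 13 above 0, percentile 98.44, and 97.01 without the _s_at and _x_at probe sets), with HSPE1 at 0.53 and HSPH1 at 0.52.

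On the lower side, targets of ATF4, the transcription factor of the integrated stress response, had a median of -0.92 (percentile 0), with 15 of 20 members below 0 and 9 at least 2-fold below. Besides CHAC1 and DDIT3, these included SESN2, a stress-induced inhibitor of mTORC1 signalling (-2.30), and DDIT4 (-2.18), another such inhibitor, whereas STC2 of the same list was at 1.08. Targets of NF-kB had a median of -0.85 (percentile 0), with 17 of 18 members below 0, and IRF1, an interferon regulatory factor, and TNF, the inflammatory cytokine, had values of -2.55 and -2.15. Lysosome genes had a median of -0.55 (14 of 19 below 0, percentile 0), with the protease genes CTSA at -1.49 and CTSD at -1.08. All 7 measured metallothioneins, which bind metal ions, lay below 0 (median -0.70, percentile 0.02), with MT1X at -1.25. Of their 11 probe sets, 9 had the suffix _x_at, which can match more than 1 of these related transcripts, so the 7 values are not independent measurements. Cholesterol synthesis genes had a median of -0.30 (14 of 19 below 0, percentile 0.25) and MVD, an enzyme of the mevalonate pathway, a value of -1.20, but SQLE (1.21) and STARD4 (1.21) of the same list were at least 2-fold higher. Immediate early genes had a median of -0.19 (17 of 23 below 0, percentile 1.61), with the AP-1 subunits JUNB at -1.87 and JUN at -1.63 (-0.78 for JUN in that comparison without the _s_at and _x_at probe sets), while FOS, another AP-1 subunit, read 0.49 and MYC, also of this list, was higher. In the p53 target list (median -0.23, 10 of 17 below 0, percentile 1.35), CDKN1A, the cell cycle inhibitor p21, had a value of -1.09 and FAS, a death receptor, one of 1.69, and the percentile was 42.84 without the _s_at and _x_at probe sets. Luminal markers (median -0.20, 12 of 18 below 0, percentile 2.45), LXR targets (median -0.29, 7 of 10 below 0, percentile 1.77) and Notch targets (median -0.23, 10 of 14 below 0, percentile 1.94) lay just below their random ranges, with TFF3, a secreted trefoil peptide, at -1.97, NR1H3, which encodes LXR alpha, at -0.91 and HES1, a repressor downstream of Notch, at -0.88. These 3 calls were lost when probe sets were averaged, at percentiles of 3.28, 3.53 and 3.72, and those of luminal markers and Notch targets also without the _s_at and _x_at probe sets, at 5.18 and 5.14. Beside each of these groups stand the control differences between the estradiol and vehicle arrays. These were 18S ribosomal RNA at 1.86, polyadenylated spikes at 0.70 and the 3' minus 5' signal of ACTB at -0.78.

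In total, 656 of 19775 genes (3.32%) differed by at least 2-fold in the values as deposited, 314 higher and 342 lower on the estradiol array. Of 294 such genes with several probe sets, 259 (88.1%) had all probe sets on the same side of 0, and 54 had every probe set past the cutoff. Here and in the other comparisons, genes were picked by the median of these same probe sets, which favours a shared sign. The share on the same side is therefore no independent check, and none was computed for shuffled probe sets. Lists stood apart in 14 of 41 cases, where 2.05 were expected for lists of independently varying genes. Members of a list can vary together and some lists share genes. Any difference between 2 single cultures can therefore give more than 2.05.

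The second comparison asks how tamoxifen differed from vehicle at the same dose and time. The lowest genes were again CHAC1 (13.0-fold lower on the tamoxifen array), INHBE, an inhibin subunit (10.8-fold), DDIT3 (7.16-fold) and CCL20 (6.29-fold), together with TFF1 (7.22-fold lower). ANXA3, an annexin, was 6.07-fold higher, ASPM, a mitotic spindle protein, 5.59-fold, SYBU 4.95-fold and GJA1 4.85-fold. The 3 ASPM probe sets ranged from 1.43 to 3.80, and its log2 value was 3.13 instead of 2.48 without the _s_at and _x_at probe sets. SLC39A6, a zinc transporter, was 5.10-fold higher over 4 probe sets that ranged from 0.17 to 3.36, and its value was 1.36 instead of 2.35 without the _s_at and _x_at probe sets. NFAT5, an osmotic stress transcription factor, also ranked among the 12 highest at 2.15, but the 1 of its 3 probe sets without the suffix _s_at read -0.10.

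The estrogen-induced list lay slightly below the all-gene median on the tamoxifen array (median -0.17, 21 of 37 members below 0, percentile 1.09), and its members went both ways. TFF1, RAPGEFL1, a guanine nucleotide exchange factor (-1.38), and ABCA3, a lipid transporter (-1.15), were at least 2-fold lower. MYC (1.14), PGR (1.07) and CXXC5 (1.01) were at least 2-fold higher. SIAH2 (-0.14), EGR3 (-0.29), CXCL12 (-0.55), GREB1 (0.46) and PDZK1 (0.085) differed by less than 2-fold. The GREB1 probe sets were of both signs here, from -0.58 to 0.59. The 2 CCND1 probe sets read 1.21 and -0.96.

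The G2/M list again stood above random lists (median 0.59, 17 of 20 above 0, percentile 100), with CDK1 at 1.70, CENPE at 1.20 and TOP2A at 1.19. Fibroblast markers had a median of 0.32 (9 of 13 above 0, percentile 99.61), led by the matrix genes LUM (0.75) and COL6A3 (0.53), and this call was lost without the _s_at and _x_at probe sets (percentile 96.98) and with probe sets averaged (96.04). ATF4 targets had a median of -0.97 (18 of 20 below 0, 10 at least 2-fold, percentile 0), with SESN2 at -2.15 and SLC3A2, an amino acid transporter subunit, at -1.94. NF-kB targets had a median of -0.65 (15 of 18 below 0, percentile 0), with TNF at -2.39 and TNFAIP3 at -2.34. Immediate early genes had a median of -0.56 (18 of 23 below 0, percentile 0), with IER2 at -1.76 and EGR1 at -1.18, and lysosome genes one of -0.57 (14 of 19 below 0, percentile 0), with CTSA at -1.33. Targets of NRF2, which governs antioxidant genes, had a median of -0.41 (14 of 16 below 0, percentile 0.01), with OSGIN1 at -1.98 and HMOX1, heme oxygenase, at -1.28. The 7 metallothioneins, mostly measured by such _x_at probe sets, lay below 0 (median -0.65, percentile 0.11), and cholesterol synthesis genes had a median of -0.39 (14 of 19 below 0, percentile 0.02), with MVD at -0.92 and DHCR7, an enzyme of the last steps, at -0.78, while the 2 members past 2-fold were higher, SQLE at 1.04 and STARD4 at 1.23. G1/S genes (median -0.25, 13 of 20 below 0, percentile 0.83) included the replication factors CDT1 at -1.30 and MCM5 at -0.96, but also CCNE2, a cyclin, at 1.39. Luminal markers (median -0.31, 13 of 18 below 0, percentile 0.23) included TFF3 at -1.64, and ribosome biogenesis genes (median -0.26, 10 of 15 below 0, percentile 1.46) included NOP2 at -0.91. Notch targets (median -0.25, 10 of 14 below 0, percentile 1.74), with HEY2 at -1.11 (-0.56 without the _s_at and _x_at probe sets) and MAML2 at 1.29, and oxidative phosphorylation genes (median -0.22, 13 of 19 below 0, percentile 2.07), with UQCRC1 at -0.81, lost their calls without the _s_at and _x_at probe sets, at percentiles of 19.11 and 7.96. As for estradiol, these groups stand beside 18S ribosomal RNA at 1.96, polyadenylated spikes at 0.49 and the 3' minus 5' signal of ACTB at -0.77 relative to vehicle.

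As deposited, 645 genes differed by at least 2-fold, 428 higher and 217 lower on the tamoxifen array (66.4% higher). After subtraction of the all-gene median the count was 679, with 326 higher and 353 lower (48.0% higher), so the split between directions depends on the centring. All probe sets lay on the same side of 0 in 264 of 320 genes (82.5%) with several, and 55 had every probe set past the cutoff. Lists stood apart in 15 of 41 cases.

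**Figure D2:**
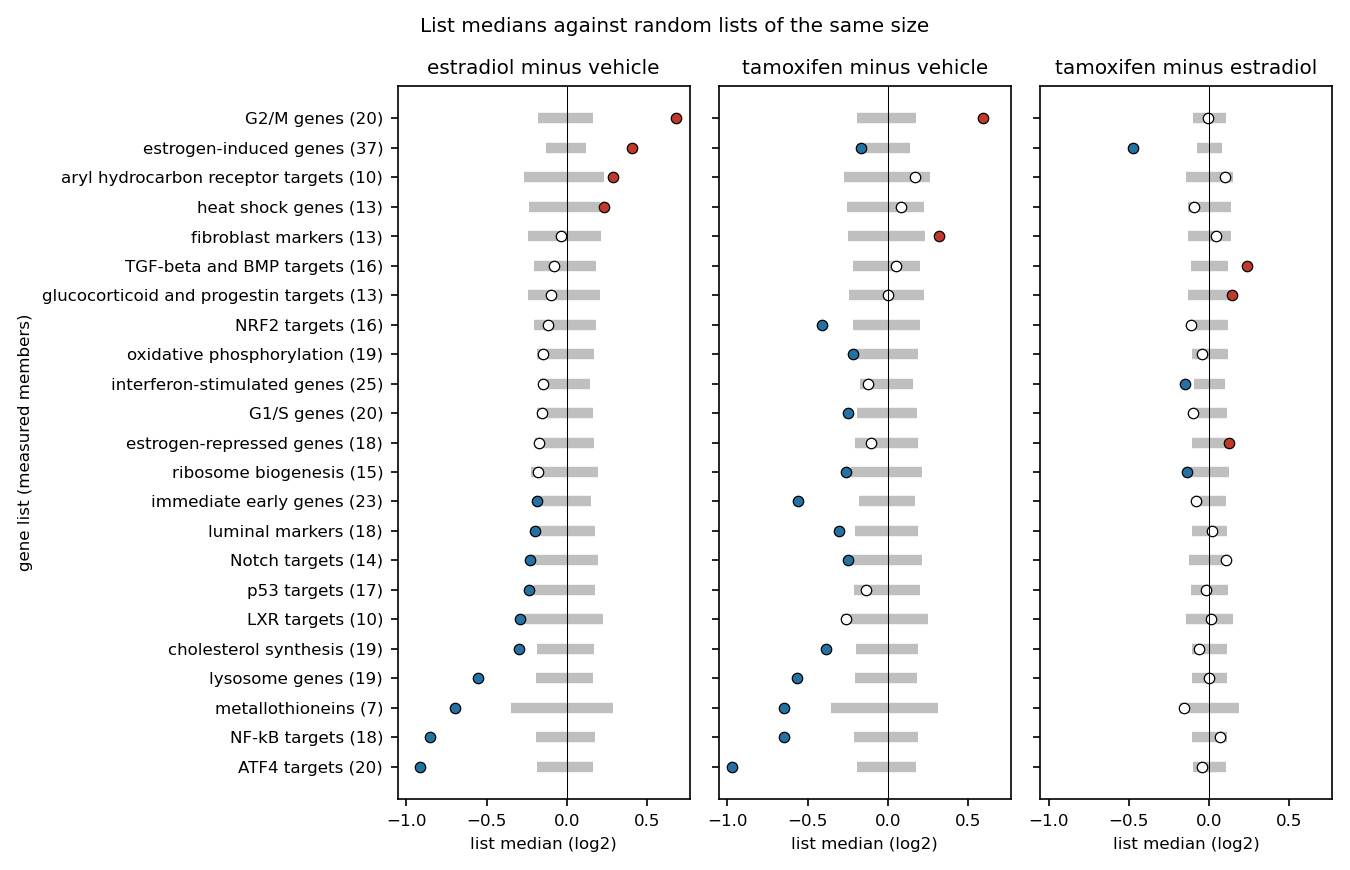
Median log2 difference (x axis, relative to the all-gene median) of the 23 gene lists that stood apart in at least 1 comparison (y axis, measured members in parentheses), in a panel per comparison. Grey bars span the central 95% of 10000 random lists of the same size, filled points lie outside that range (red above, blue below) and open points inside; ATF4 targets lie near -0.92 and -0.97 in the 2 comparisons with vehicle, and estrogen-induced genes at -0.48 between tamoxifen and estradiol.

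The differences of the 2 treated arrays from vehicle were set against each other to see how far the treatments coincided. CHAC1, DDIT3, TNFAIP3 and FOLR1, a folate receptor, were low on both treated arrays, and SYBU, GJA1, ANXA3 and FAM83D, a spindle protein, were high on both. At least 2-fold differences in both comparisons were shared in direction by 234 genes on the higher side, against 6.80 expected for independent lists of these sizes, and by 141 on the lower side against 3.75. No gene passed the cutoff in opposite directions. With a shared vehicle array, this would need the treated arrays to differ by both cutoffs together, so the absence says little about like responses. A probe set of TWSG1, a modulator of BMP signalling, did read 1.24 for estradiol and -1.20 for tamoxifen, while its other probe set read 0.60 and 0.36. Across genes, which are not independent replicates, the correlation was 0.848 (Pearson) and 0.795 (Spearman). Unchanged arrays simulated against a shared vehicle array gave a mean correlation of 0.4998 and 0 shared genes. The covariance was 0.159 against 0.0268 simulated, a difference of 0.132. Equal noise on every array fixes the simulated correlation in advance. The noise was normal, at an SD of 0.232 for a difference between 2 arrays, which puts almost no gene past the cutoff. Between the treated arrays themselves 42 genes passed it, so the 0 shared genes are no reference for the observed counts. The simulated noise came from the tamoxifen minus estradiol differences, so the simulated correlation and covariance are too low if the vehicle array was noisier. The vehicle array could not be split, so part or all of the excess may come from the shared control. In 350 genes the vehicle array lay at least 2-fold from both treated arrays while these differed by less than 0.5 on the log2 scale, with the vehicle array higher in 131 and lower in 219 (181 and 203 after subtraction of the all-gene medians). The estradiol array stood apart in this way in 9 genes and the tamoxifen array in 12.

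**Figure D3:**
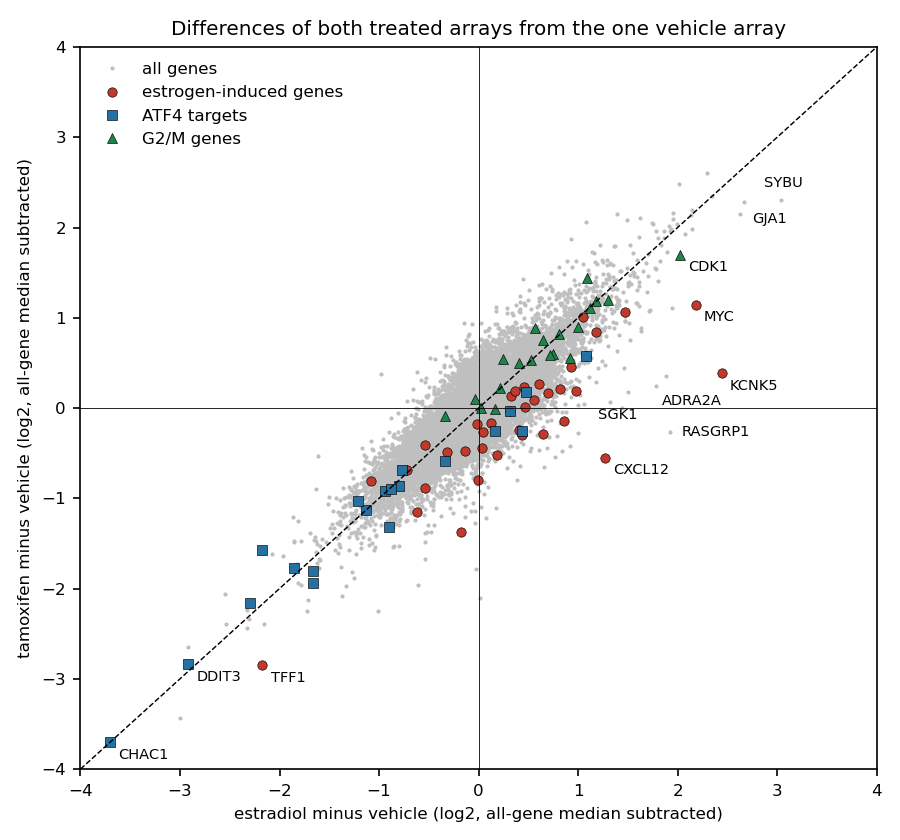
Log2 difference from vehicle on the tamoxifen array (y axis) against that on the estradiol array (x axis), both relative to the all-gene median, with a grey point per gene for 19775 genes, members of 3 lists in colour and equality as a dashed line. ATF4 targets such as CHAC1 lie near the line at the lower left and G2/M genes at the upper right, whereas KCNK5, RASGRP1 and CXCL12 lie below the line.

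Tamoxifen was also compared directly with estradiol, which asks whether the modulator gave the response of the natural ligand. Among the lowest genes on the tamoxifen array were RASGRP1, a Ras activator (4.55-fold lower than on the estradiol array), ZSWIM9 (4.34-fold), KCNK5 (4.17-fold), CXCL12 (3.53-fold), ADRA2A, an adrenergic receptor (2.92-fold), and SGK1, a serum and glucocorticoid regulated kinase (log2 difference -1.32). Both CXCL12 probe sets showed this difference, at -2.13 and -1.51. On the higher side the differences were smaller, with SHISA2 2.55-fold, AMIGO2, an adhesion molecule, 2.10-fold, BAMBI, a pseudoreceptor that dampens TGF-beta signalling, 2.05-fold and DKK1, a secreted Wnt inhibitor, 1.97-fold higher.

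Among the 37 estrogen-induced genes, 34 were lower on the tamoxifen than on the estradiol array, 14 of them at least 1.5-fold and 5 at least 2-fold, and none was 1.5-fold higher. As deposited, 33 of 37 lay below 0, 11 of them at least 1.5-fold and 3 at least 2-fold. The list median was -0.48, below all 10000 random lists (percentile 0). Besides KCNK5 and CXCL12, RAPGEFL1 (-1.21), MYC (-1.04) and SIAH2 (-1.001) were lowest, and the next fixed genes were EGR3 (-0.95), GREB1 (-0.74), TFF1 (-0.69), PDZK1 (-0.48) and PGR (-0.41). The 3 GREB1 probe sets ranged from -1.19 to -0.35. MYC and PGR were thus above vehicle on both treated arrays, with the lower value on the tamoxifen array, and TFF1 was below vehicle on both. Estrogen-repressed genes had a median of 0.12 (13 of 18 above 0, percentile 98.34), with CITED2, a transcriptional coregulator, at 0.59 (0.38 without the _s_at and _x_at probe sets) and BMF, a pro-apoptotic factor, at 0.35.

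Targets of TGF-beta and BMP signalling stood above random lists (median 0.24, 10 of 16 above 0, percentile 99.98), with BAMBI at 1.03, SMAD7, an inhibitory SMAD, at 0.53, and the inhibitors of differentiation ID2 and ID1 at 0.57 and 0.49, while KLF10 of the same list was at -1.001. Interferon-stimulated genes lay below (median -0.15, 16 of 25 below 0, percentile 0.07), with IFIT1 at -0.57 and IFIH1 at -0.67, and 14 of 25 lay below 0 as deposited. Ribosome biogenesis genes lay below (median -0.14, 13 of 15 below 0, or 8 of 15 as deposited, percentile 1.51), with NOP2 at -0.42 and NCL, nucleolin, at -0.41, and this call was lost with probe sets averaged (percentile 2.99). Glucocorticoid and progestin targets had a median of 0.14 (8 of 13 above 0, percentile 98.16) but a mean of -0.067 relative to the all-gene mean, with SGK1 low while CEBPD, a C/EBP transcription factor, was at 0.46 and NFKBIA at 0.23. That call was lost without the _s_at and _x_at probe sets (percentile 94.63). Groups that were low against vehicle and did not stand apart here included ATF4 targets (median -0.042), NF-kB targets (0.070), metallothioneins (-0.15, 6 of 7 below 0, percentile 4.38) and lysosome genes (0.0011), and G2/M genes had a median of -0.0099. NF-kB targets did stand above random lists without the _s_at and _x_at probe sets (percentile 99.67) and with probe sets averaged (97.92).

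**Figure D4:**
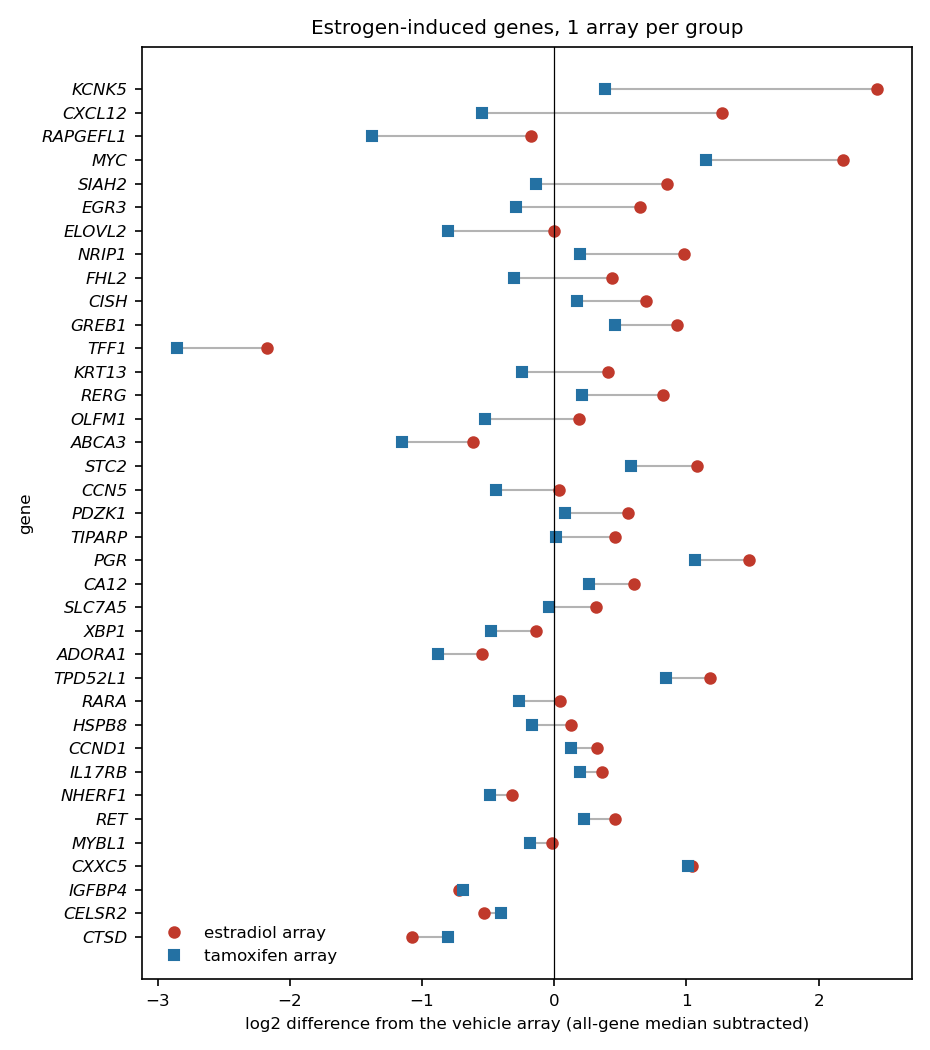
Log2 difference from the vehicle array (x axis, relative to the all-gene median) of the 37 measured estrogen-induced genes (y axis) on the estradiol array (circles) and the tamoxifen array (squares), 1 array per group, with grey lines joining the values of a gene. Genes are ordered by the tamoxifen minus estradiol difference, which is lowest for KCNK5 (-2.06) and CXCL12 (-1.82), and TFF1 lies at -2.17 and -2.85.

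The vehicle array does not enter this comparison, but the 9 first hybridisation spike probe sets had a median of -3.16 on the tamoxifen relative to the estradiol array. The 9 r2 probe sets of the same spikes had one of 0.49.

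Between these 2 arrays 42 genes (0.212%) differed by at least 2-fold as deposited, 18 higher and 24 lower on the tamoxifen array (42.9% higher). After subtraction of the all-gene median there were 45, with 5 higher and 40 lower (11.1% higher). Of the 42 genes, 34 had 1 probe set, among them RASGRP1, ZSWIM9, KCNK5, ADRA2A and SGK1, so no second probe set checks them. Over all genes, 9252 of 19775 had 1 probe set. Of 8 genes past the cutoff with several probe sets, 7 had all on the same side of 0 and 3 had every probe set past it. In this comparison 2 random probe sets of the same gene correlated at 0.0994 across genes. Among the 9 genes in which the estradiol array stood apart, 8 were highest there, namely KCNK5, CXCL12, RASGRP1, ADRA2A, SGK1, KCTD6, RBM24 and USP3-AS1, and AMIGO2 was lowest. Among the 12 in which the tamoxifen array stood apart, 6 were highest there, including DKK1, EPHA4 and NR2F1, and 6 lowest, including HEY2, RAPGEFL1 and TMEM138. After subtraction of the all-gene median, 10 genes were highest and 0 lowest on the estradiol array, without AMIGO2, and 0 were highest and 11 lowest on the tamoxifen array. USP3-AS1, and the members SQLE, STARD4, STC2, FAS, CXXC5, CCNE2, MAML2 and KLF10, which were at least 2-fold from the all-gene median against the direction of their lists, were named after their values were seen. Lists stood apart in 6 of 41 cases against 2.05 expected for lists of independently varying genes, a number that members varying together can exceed.

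The remaining 18 lists stood apart in no comparison, with medians from -0.20 to 0.14 and percentiles from 3.16 to 97.42. They were nuclear receptors and cofactors, MAPK feedback genes, pluripotency genes, stem cell and mesenchymal genes, basal markers, immune cell markers, endothelial markers, fatty acid synthesis, endoplasmic reticulum chaperones, hypoxia targets, apoptosis regulators, Wnt targets, autophagy genes, ribosomal proteins, splicing factors, circadian clock genes, tamoxifen metabolism and housekeeping genes. Among the pluripotency genes, SOX2 had values of 0.00070, 0.073 and 0.024 in the 3 comparisons and NANOG -0.22, -0.089 and 0.12, while KLF4 read -0.20, -0.68 and -0.48 from 2 probe sets. For estradiol minus vehicle the KLF4 probe sets had opposite signs, at 0.54 and -0.94, as did those of NANOG, at 0.083 and -0.52. KRT18, an epithelial keratin, had values of 0.00052, -0.094 and -0.10, VIM (vimentin) 0.48, 0.33 and -0.15, and HMGCS1, an enzyme of cholesterol synthesis, -0.072, -0.14 and -0.071. The HMGCS1 values are medians of 2 probe sets of opposite sign, which read 0.33 (suffix _s_at) and -0.60 (suffix _at) for tamoxifen minus vehicle.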

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

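All tests below were chosen after the result was seen, except those of gene length and of probe sets that can match several transcripts.

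Control probe sets, which lie outside the comparisons of genes, differed between the arrays. On the estradiol and tamoxifen arrays, respectively, 18S ribosomal RNA stood 1.86 and 1.96 above vehicle on the log2 scale, the 5' (but not the 3' or middle) probe set of 28S ribosomal RNA 2.08 and 2.20, and the polyadenylated spikes 0.70 and 0.49. The 3' minus 5' signal was -0.78 and -0.77 for ACTB and -0.53 and -0.54 for GAPDH. The first hybridisation spike probe sets differed by -3.23 on the tamoxifen array.

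The first pattern is that both treated arrays shared differences from the vehicle array, such as low ATF4 and NF-kB targets and high G2/M genes. For single genes in which the vehicle array stood apart, a shift shared by genes of similar length was argued against as the whole cause. There were 321 such genes after the median of length bins was subtracted, against 349 before, and 297 genes were in both counts. Subtracting bin medians leaves in place a spread that differs with length, which was not tested. List medians were not recomputed after that subtraction, so this test does not bear on the named lists. A difference in labelling between the vehicle array and the treated arrays goes with the polyadenylated spikes. Their median was 0.698 for estradiol minus vehicle, against an all-gene spread of 0.330. These spikes are bacterial and cannot show the quality of the cells' RNA. The 3' minus 5' signal on the estradiol and tamoxifen arrays relative to vehicle was -0.78 and -0.77 for ACTB and -0.53 and -0.54 for GAPDH. The vehicle array thus had the relatively stronger 3' signal, which goes with a difference in RNA quality or labelling. The spike signal may also depend on how much messenger RNA the cells contributed, which was not tested. Which side was unusual is not settled. Around the subtracted centre the vehicle array had the smallest spread over probe sets, at 0.140 against 0.248 for estradiol and 0.304 for tamoxifen. The arrays behind that centre are unknown. A response of the cells to both compounds, or a state of the vehicle culture, remains open as a biological explanation and cannot be told apart with 1 vehicle array: the estrogen-induced list lay at percentile 1.09 for tamoxifen against vehicle, which does not bear on ATF4 or NF-kB targets. Both kinds of explanation may hold at once.

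The second pattern is that estrogen-induced genes were lower on the tamoxifen than on the estradiol array. A constant shift of the whole array could not move the list percentile, which was taken among random lists from the same arrays. The median of all genes as deposited was 0.115, in the opposite direction to the list, and adds no support for that reason. Probe sets that can match several transcripts were argued against by a median of -0.479 over the 26 members left without them. RNA quality was argued against by the 3' minus 5' signal of ACTB, which differed by 0.0058 between these arrays. A difference in labelling was not excluded, since all 24 polyadenylated spike probe sets were lower on the tamoxifen array. Their median was -0.15 as deposited, where that of all genes was 0.115, so relative to all genes the spikes lay lower still. These probe sets measure only the dap, lys, phe and thr transcripts and are not independent readings. A difference between individual cultures unrelated to the compounds stays open, since 34 of 37 members lying below 0 on 1 pair of arrays cannot be told apart from it. Against vehicle, the median of the whole list was 0.41 for estradiol and -0.17 for tamoxifen. For the 26 members it was 0.0087 for estradiol (percentile 55.12), so a rise with estradiol that tamoxifen weakened is not shown for them. Lower levels of these genes with tamoxifen than with estradiol are a hypothesis that replicate cultures could test.

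The third pattern is the low signal of the first hybridisation spike probe sets on the tamoxifen array. Omission or under-dosing of these spikes was argued against by the 9 r2 probe sets of the same spike transcripts, whose median was 0.218 above vehicle on that array. No biological explanation was tested, since the spikes do not come from the cells.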

How the results depend on the processing

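The median over probe sets, a cutoff of 1.5-fold, leaving out _s_at and _x_at probe sets and the rank correlation were planned before the data were examined. The mean over probe sets, all-gene median subtraction, 4 all-gene spreads, every one of several probe sets past the cutoff and lists matched on probe sets per gene were chosen after. Not run, because levels are not in the values, were the level filter at the median or upper quartile, the probe set with the highest mean, spreads within level bins, loess centring, quantile normalization and a constant added to linear values. The setting without a level filter is the one reported. Signal over background is unknown, which limits every fold. In the order estradiol minus vehicle, tamoxifen minus vehicle and tamoxifen minus estradiol, the counts of 656, 645 and 42 genes became 3011, 3063 and 546 at 1.5-fold, 193, 153 and 113 at 4 all-gene spreads, and 54, 55 and 3 with every one of several probe sets past the cutoff. Other totals, and the correlation, stayed within 1.5 times, but subtraction of the all-gene median moved the splits by direction further, to 353 lower from 217 in tamoxifen minus vehicle and to 5 higher and 40 lower from 18 and 24 in tamoxifen minus estradiol.

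Of 35 calls of a list as standing apart in a comparison (23 lists), 24 held under the alternatives run for them, among them 2 of metallothioneins, for which too few members were left without _s_at and _x_at probe sets. Without _s_at and _x_at probe sets, calls were lost for estrogen-induced genes (percentile 55.12), luminal markers (5.18), heat shock genes (97.01), p53 targets (42.84) and Notch targets (5.14) in estradiol minus vehicle, for fibroblast markers (96.98), Notch targets (19.11) and oxidative phosphorylation (7.96) in tamoxifen minus vehicle, and for glucocorticoid and progestin targets (94.63) in tamoxifen minus estradiol. Lists that then stood apart were estrogen-repressed genes (0.4), NRF2 targets (0.98) and apoptosis regulators (0.95) in estradiol minus vehicle, fatty acid synthesis (1.95) and LXR targets (0.34) in tamoxifen minus vehicle, and immune cell markers (98.02), heat shock genes (1.78), NF-kB targets (99.67) and ribosomal proteins (1.81) in tamoxifen minus estradiol. With probe sets averaged, calls were lost for luminal markers (3.28), LXR targets (3.53) and Notch targets (3.72) in estradiol minus vehicle, fibroblast markers (96.04) in tamoxifen minus vehicle, and glucocorticoid targets (97.11) and ribosome biogenesis (2.99) in tamoxifen minus estradiol. Calls were gained for LXR targets (1.49) in tamoxifen minus vehicle and for immune cell markers (98.43), NRF2 targets (2.35), G1/S genes (2.06) and NF-kB targets (97.92) in tamoxifen minus estradiol. Random lists matched on probe sets per gene added immune cell markers (97.85) and apoptosis regulators (98.21) in tamoxifen minus estradiol, LXR targets (1.61) in tamoxifen minus vehicle and apoptosis regulators (0.77) in estradiol minus vehicle. NFAT5 reversed to -0.10 in tamoxifen minus vehicle without _s_at and _x_at probe sets, which left 1 probe set. Of named genes under 2-fold, CCND1 also changed sign there, to -0.33 in estradiol minus vehicle and -0.96 in tamoxifen minus vehicle, as did COX5B in tamoxifen minus vehicle (to 0.21) and SMAD6 and ESR1 in tamoxifen minus estradiol (to -0.060 and 0.012). Of 178 values of named genes that could be computed in that setting, 21 besides NFAT5 moved by more than the all-gene spread, as did 6 of 239 with probe sets averaged. The causes of the other changes were not tested.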

Other observations

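Probe sets of some named genes disagreed. CCND1 read 0.98 and 1.21 with its _s_at probe set on the estradiol and tamoxifen arrays relative to vehicle, and -0.32 and -0.96 with its _at probe set. TWSG1, which modulates BMP signalling and ranked among the 12 lowest for tamoxifen minus estradiol, read -2.44 with its _s_at probe set and -0.24 with its _at probe set. The 4 CDK1 probe sets spanned 0.29 to 3.68 for tamoxifen minus vehicle.

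Gene length correlated with the difference from vehicle across genes, at a Spearman coefficient of 0.211 for estradiol and 0.197 for tamoxifen, and at -0.0075 between the treated arrays. The coefficients cover 19738 genes with a genomic length, which are not independent replicates.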
